A study of Macaca fascicularis with 49 samples.

How the data were processed

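The series measured gene expression in tracheal brushings of 9 cynomolgus macaques (Macaca fascicularis). Per the series text, the tissue was collected at necropsy, placed in multi-well plates and given either a mock control or poly I:C, a synthetic double-stranded RNA used to mimic a viral infection. The sample labels give a dose of 100 ug for mock and poly I:C samples alike, while the series text gives the same figure in milligrams, so the dose is uncertain in its unit. The time between stimulation and collection is not given in the sources used here. The series text also speaks of nasal scrapes and lung tissue, which were not analysed here.

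Per the labels' protocols, total RNA was extracted with a column kit under a fibrous tissue protocol that includes a proteinase K step, and was amplified and biotin-labelled with a 3' in vitro transcription kit. The RNA was hybridised to arrays whose probe sets, by the platform annotation, are those of a human expression array. A macaque transcript that differs from the human probe sequence can therefore give a low signal, and levels of different probe sets are not a measure of which transcript is more abundant. RMA is named in the submitters' processing notes, without a version. RMA subtracts background, makes the arrays' distributions alike and summarises the probes of a probe set. The deposited values are on a log scale and were read as log2, from their range and from what RMA gives, since the base is not stated. Because RMA makes the distributions of the arrays alike, a change shared by most transcripts would not show.

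The deposited table held 4 control probe sets and 17886 other probe sets on 49 arrays, and how these probe sets were chosen is not given in the sources used here. Of the 17886, 16132 had 1 gene symbol in the platform annotation, 412 had several and 1342 were not named there. Human symbols were kept as the annotation gives them, and no genome coordinates are printed because the annotation holds none. For gene counts and gene lists, a gene was represented by its probe set with the highest mean over all arrays, among those with a single symbol, which gave 10277 genes. Of these, 3847 had 2 or more probe sets. The table held no identical columns and 0 columns without a sample.

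Arrays were grouped by the animal, technical replicate and treatment in the labels into 24 mock and 25 poly I:C arrays. Animals 1 and 2 had 2 arrays per treatment, animal 9 had 2 mock and 3 poly I:C arrays, and every other animal had 3 of each. Technical replicates are not independent animals, so they were averaged, and n is 9 animals unless arrays are named. The animals were checked as pairs: deviations from the treatment mean correlated within an animal in 9 of 9 animals (r from 0.233 to 0.700) and had a median r of -0.072 between animals. Equal technical replicate numbers did not pair the arrays within an animal (median r -0.048). Arrays have no read depth, and the number of animals and arrays limits the precision.

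Poly I:C was compared with mock in limma 3.58.1 (R 4.3.3) on the averages, with the animal as a block, moderated variances and Benjamini-Hochberg adjustment over 17886 probe sets. A probe set was called at an adjusted p under 0.05. Differences are poly I:C minus mock on the log2 scale, with the standard error of that fit, and levels are means ± SD over animals. Whether the response differed between animals was tested in limma on all 49 arrays with a mean for each animal and treatment and an F-test of the interaction. That test has 31 residual degrees of freedom, and its error is the spread between technical replicates only. The same fit gave the changes within each animal. Before the data were examined, 34 gene lists were fixed, covering interferon and antiviral genes, inflammation, antigen presentation, epithelial cell types, stress and metabolism, and markers of leukocytes, stroma, vessels and blood. Each was tested against all other genes with camera at a preset correlation of 0.01, with an estimated correlation, and with fry. Fry asks only whether a list's genes move on balance in a direction. Adjustment was over the 34 lists.

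The named genes follow a rule fixed before the data were examined. It took a list of 34 genes of interest, the 10 largest rises and 10 largest falls among called genes that moved alike in all 9 animals, 2 to 4 members of each gene list, and the 10 genes with the smallest interaction p. Unnamed transcripts and symbols of uncharacterised loci were left out. Members that make up a count of 5 or fewer are named too and, where the rule does not give them, were chosen after their values were seen. Genes of interest without a single-gene probe set in the table used, among them IFNB1, CXCL11, TLR3, TP63, ACTB and GAPDH, were not analysed here. The result of 1 further gene of interest, withheld for evaluation, is not reported here.

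Correlations across animals used Pearson's r and Spearman's rho with exact permutation p-values in Python 3.11.15 (numpy 2.4.6, scipy 1.17.1), and figures were drawn with matplotlib 3.10.9. The fits were tested on simulated data. For the treatment comparison on 17886 simulated probe sets, 52% of probe sets changed by 0.25 log2 were recovered, 88% at 0.5 and 100% at 1, with 7.10% false calls. For the difference between animals on 17886 simulated probe sets, 6% were recovered when the response of an animal differed by 0.5 log2, 68% at 1 and 92% at 1.5. Each size was given to 50 probe sets, and noise was drawn independently for each probe set. In the real data more probe sets were called and members of a list were correlated, so these rates need not hold there. Alternatives left out the block, the averaging, dim probe sets or single animals, and changed the scaling, the variance model, the array weights and the threshold. A further set left out the array labelled poly I:C 7.3 or animal 7 and was chosen after seeing the data.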

Results

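Tracheal brushings from 9 cynomolgus macaques were kept in culture wells and given mock control or poly I:C, a synthetic double-stranded RNA that cells sense as they do viral RNA. Expression was read on 49 arrays, 24 mock and 25 poly I:C, with 2 or 3 technical replicates per animal and treatment. Technical replicates correlated with a median r of 0.982 over 44 pairs (0.905 to 0.992). Array medians lay between 5.94 and 6.04 log2 in mock and between 5.91 and 6.03 in poly I:C. The comparison asked which airway transcripts respond to double-stranded RNA, and whether the 9 animals responded alike.

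Poly I:C raised antiviral effectors, type III interferons and several genes that are in none of the 34 gene lists. IFIT2, an interferon-induced protein that binds viral RNA, rose from 5.81 ± 1.61 to 10.43 ± 0.73 log2 (SD, n = 9), a difference of 4.63 (SE 0.47, adjusted p = 3.1e-05). IFNL1, a type III interferon, rose from 3.97 ± 0.32 to 7.70 ± 1.32 (difference 3.73, SE 0.37, adjusted p = 2.8e-05), and IFNL2 rose by 1.86 (SE 0.37). OASL, an antiviral protein of the oligoadenylate synthetase family, rose 10.6-fold (log2 3.40, SE 0.36), and HERC5, the ligase that attaches ISG15 to proteins, rose 2.95-fold. IL6, an inflammatory cytokine, rose 2.63-fold, from 8.13 ± 0.91 to 9.53 ± 0.58. Of genes in none of the 34 lists, the probe set annotated to RPPH1, the RNA subunit of ribonuclease P, read 4.71-fold higher. That its signal comes from this RNA was not checked. KCNE4, a potassium channel subunit, rose 2.94-fold. AP2B1, a clathrin adaptor subunit, rose 2.60-fold and ETV3, a transcriptional repressor, 2.52-fold. Whether these rises are separate from the interferon response was not tested. Each gene of this paragraph was higher after poly I:C in 9 of 9 animals, as the rule for the largest rises requires. IFNL1, IFNL2, IL6, RPPH1, AP2B1 and HERC5 are read by a single probe set each, which was not checked for cross-hybridisation.

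In all, 2960 probe sets were higher and 3596 lower after poly I:C, which is 36.7% of the 17886 tested (limma, animal as a block, adjusted p under 0.05). By gene, 1845 rose and 1683 fell. Most changes were small: 6232 of the 6556 called probe sets changed by less than 1.5-fold, and the median absolute difference of all called probe sets was 0.24 log2. The 5' control probe set for ACTB was 0.119 lower after poly I:C in 9 of 9 animals (exact permutation p = 0.00391), and a difference in RNA quality or labelling between treatments was not excluded for changes of this size. Changes of 2-fold or more were called for 52 probe sets, 42 higher and 10 lower. Without the animal as a block, 1652 probe sets were higher, 1936 lower and 46 changed 2-fold or more.

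**Figure D1:**
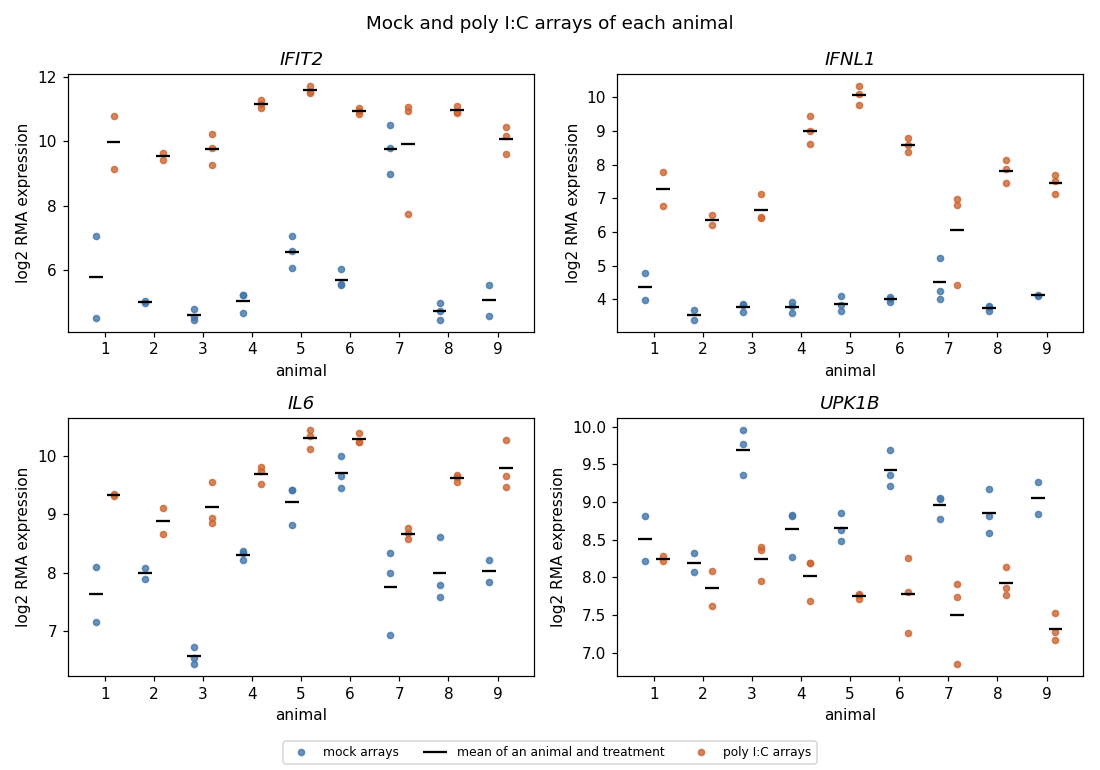
Expression of 4 genes on each array in log2 RMA units (vertical axis) by animal (horizontal axis), with mock arrays in blue, poly I:C arrays in orange, and a bar at the mean of each animal and treatment. IFIT2 rose by 4.63, IFNL1 by 3.73 and IL6 by 1.39 log2 on average and UPK1B fell by 1.04, while the 3 mock arrays of animal 7 already lie high for IFIT2.

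The interferon-stimulated genes moved upward as a group. Of 49 measured members, 34 rose (37 adjusted over the list alone) and 15 did not pass, with a median difference of 0.52 log2. IFI44, of unknown biochemical function, rose by 2.79 (SE 0.38), IFIT1 by 2.57 (SE 0.45) and ISG15, a ubiquitin-like modifier, from 8.18 ± 0.61 to 9.49 ± 0.34, each in 8 of 9 animals. RSAD2, an antiviral enzyme, rose by 0.59 (SE 0.20) and OAS1 by 0.66 (SE 0.21), each in 7 of 9 animals, and only 1 of the 2 OAS1 probe sets passed. MX1 was 0.15 higher (SE 0.10, adjusted p = 0.235). The list stood apart from other genes by camera (adjusted p = 3.3e-11) but not with an estimated correlation (adjusted p = 0.702). Without the array labelled poly I:C 7.3, which lay closer to mock arrays, 38 members rose.

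Some interferon and receptor genes, double-stranded RNA sensors and interferon regulatory factors also rose. Of 7 measured interferon and receptor genes, 4 rose (4 higher and 1 lower adjusted over the list alone), namely IFNL1, IFNL2, the lambda receptor chain IFNLR1 (0.27, SE 0.08) and IFNGR2 (0.20, SE 0.06). That list did not pass camera (adjusted p = 0.230). Of 18 genes of double-stranded RNA sensing, 9 rose and 2 fell, with the same counts adjusted over the list alone. The cytoplasmic sensors IFIH1 and RIGI rose by 2.30 and 2.20 (SE 0.29 each), DHX58 by 0.52 (SE 0.07) and UNC93B1 by 0.37 (SE 0.05), whereas the kinase TBK1 and its partner TANK fell by 0.22 and 0.32. This list passed camera (adjusted p = 0.0036) but not with an estimated correlation (adjusted p = 0.479) or without the members of 2 lists (adjusted p = 0.230). Of 12 interferon regulatory factors and STAT genes, 9 rose (10 adjusted over the list alone), with IRF9 up 0.63 (SE 0.10), STAT6 0.38 (SE 0.08), IRF1 0.33 (SE 0.04) and STAT5A 0.28 (SE 0.08). The second IRF1 probe set did not pass, and IRF7 differed by 0.07 (SE 0.05, adjusted p = 0.283). The list passed camera (adjusted p = 1.3e-04) and had an adjusted p = 0.063 with an estimated correlation.

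Chemokines and inflammatory mediators rose in part. Of 18 chemokines, 8 rose and 1, CXCL14, fell by 0.62, counts that were the same adjusted over the list alone. CXCL10, which draws activated T cells, rose from 4.54 ± 1.10 to 6.18 ± 0.87, CXCL3 rose by 1.09 (SE 0.19), the monocyte attractant CCL2 by 0.90 (SE 0.15), CCL20 by 0.84 (SE 0.16) and CXCL8 by 0.22 (SE 0.08). CCL5 was 0.46 higher (SE 0.19, adjusted p = 0.077). The chemokine list passed camera (adjusted p = 0.019), but not with an estimated correlation (adjusted p = 0.702), without the block (adjusted p = 0.145) or without animal 5 (adjusted p = 0.0502). Of 23 inflammatory cytokines and mediators, 10 rose and 3 fell, also adjusted over the list alone, without a shift of the list (camera adjusted p = 0.109). PTGS2, the inducible cyclooxygenase, rose by 1.05 (SE 0.23), CSF1 by 0.88 (SE 0.11) and CSF3 by 0.68 (SE 0.15), while IL1RN, EDN1 and IL19 fell by 0.45, 0.35 and 0.22. TNF differed by 0.07 (SE 0.08, adjusted p = 0.541).

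Some genes of the NF-kappaB pathway and most of those of antigen presentation on MHC class I rose modestly. Of 16 NF-kappaB genes, 8 rose (9 adjusted over the list alone), including the adhesion molecule ICAM1 (0.62, SE 0.07), NFKB1 (0.44, SE 0.06) and the feedback inhibitors NFKBIA (0.37, SE 0.06) and TNFAIP3 (0.37, SE 0.08). The list's camera test (adjusted p = 0.0047) was lost with an estimated correlation (adjusted p = 0.696) and without the block (adjusted p = 0.070). Of 15 MHC class I genes, 11 rose and the trimming peptidase ERAP1 fell by 0.23, also adjusted over the list alone. The chaperone CALR rose by 0.92 (SE 0.12), the peptide transporter TAP2 by 0.83 (SE 0.06), the immunoproteasome subunit PSMB9 by 0.53 (SE 0.06) and HLA-B by 0.52 (SE 0.05). Camera gave an adjusted p = 3.9e-05 for this list, and an adjusted p = 0.479 with an estimated correlation. In the list of 14 genes named for negative regulation of cytokine signalling, 6 rose and DUSP5 fell by 0.28, also adjusted over the list alone (camera adjusted p = 0.241). IDO1, which degrades tryptophan, rose by 0.82 (SE 0.15), SOCS3 by 0.68 (SE 0.09) and the checkpoint ligand CD274 by 0.37 (SE 0.08). TRIM25 rose by 0.57 (SE 0.08) but is also in the interferon-stimulated list, so its rise is not read as negative regulation. The SOCS1 probe set with the highest mean differed by 0.03 (SE 0.04, adjusted p = 0.630) and 1 of its other 3 passed. The death ligand TNFSF10 was 0.28 higher (SE 0.14, adjusted p = 0.141).

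Genes that fell in all animals included a plasminogen activator, membrane proteins and a keratin. PLAT, the tissue plasminogen activator, fell from 7.77 ± 0.60 to 6.61 ± 0.73 (difference -1.16, SE 0.22, adjusted p = 0.0018). UPK1B, a uroplakin of epithelial membranes, fell by 1.04 (SE 0.15), SCEL, a protein of cornified envelopes, by 1.02 (SE 0.18), LRRN1 by 1.02 (SE 0.17) and the membrane peptidase CPM by 1.00 (SE 0.21). PEG10 fell by 0.94 (SE 0.13), the heme-degrading enzyme HMOX1 by 0.90 (SE 0.16), the corepressor TLE4 by 0.89 (SE 0.10), the keratin KRT13 by 0.89 (SE 0.13) and IGDCC4 by 0.88 (SE 0.09). Each was lower after poly I:C in 9 of 9 animals, as the rule for the largest falls requires. The size of several falls differed between animals, and in animal 1 LRRN1 differed by only -0.02 and KRT13 by -0.06. PLAT differed by -1.45, -2.78, -1.64 and -1.96 in animals 3, 6, 7 and 9 and by -0.28 to -0.72 in the others (interaction adjusted p = 7.7e-04). CPM differed by -1.54, -1.99, -1.18 and -2.41 in these animals and by -0.19 to -0.48 in the others (interaction adjusted p = 2.6e-05), and SCEL by -1.45 to -1.85 and -0.21 to -0.90 (interaction adjusted p = 1.8e-04). MYBPC1 had a larger mean fall (-1.33, adjusted p = 0.0395) but was lower in 6 of 9 animals.

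Of 14 heat shock and oxidative stress genes, 7 fell, also adjusted over the list alone, among them HMOX1, the cystine transporter SLC7A11 (-0.70, SE 0.14), and both subunits of the glutathione-synthesis enzyme, GCLM (-0.48, SE 0.13) and GCLC (-0.37, SE 0.07). This list passed camera (adjusted p = 0.012) but not with an estimated correlation (adjusted p = 0.696).

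Many ciliated cell markers were higher after poly I:C and none passed as lower, while markers of other epithelial cells moved in both directions. The lists were not tested against each other. Of 31 ciliated markers, 18 rose (20 adjusted over the list alone), with CAPS up 0.88 (SE 0.07), the tektin TEKT2 0.86 (SE 0.08), TPPP3 0.65 (SE 0.07) and the dynein chain DNAI2 0.38 (SE 0.08). FOXJ1, the master regulator of motile cilia, rose by 0.20 (SE 0.05). The list passed camera (adjusted p = 1.5e-05) but not with an estimated correlation (adjusted p = 0.702), and 14 members rose without the array labelled poly I:C 7.3. Of 23 secretory and goblet markers, 3 rose and 7 fell, also adjusted over the list alone (camera adjusted p = 0.175). BPIFA1 and BPIFB1, secreted defence proteins, rose by 1.03 (SE 0.33) and 0.74 (SE 0.19), TFF1 rose by 0.55 (SE 0.14) and CEACAM5 fell by 0.61 (SE 0.10). The mucin gene MUC5AC was 0.34 higher (SE 0.31, adjusted p = 0.421), with 1 of its 3 probe sets passing, and SCGB1A1, the club cell secretory protein, differed by -0.17 (SE 0.12, adjusted p = 0.281).

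Basal cell markers showed 3 rises (BCAM 0.57, AQP3 0.50 and LAMB3 0.32) and 2 falls (the integrin ITGA6 by 0.46 and DST by 0.29) among 13, also adjusted over the list alone, with a camera adjusted p = 0.643. Among 18 squamous differentiation genes, KRT13, KRT4 (-0.64), DSG3 (-0.60), PPL (-0.43) and KRT80 (-0.24) made up the 5 falls, and SERPINB3 (0.45), CDSN (0.40) and KRT16 (0.21) the 3 rises. Adjusted over the list alone the counts were 6 and 3, and camera gave an adjusted p = 0.061. The squamous list mean differed by -0.54, -0.45, -0.60 and -0.58 in animals 3, 6, 7 and 9 and by -0.02 to 0.12 in the others. Of 16 junction genes, 4 fell, namely CLDN10 by 0.76, TJP1 by 0.46, MARVELD2 by 0.28 and CLDN1 by 0.27, and 1, CLDN8, rose by 0.28, also adjusted over the list alone (camera adjusted p = 0.241).

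Lists of markers of cells other than epithelium were examined because a brushing can hold such cells. Their members are not exclusive to these cells. LYZ and S100A9, for example, are also in the airway defence list, so a change of a member need not be a change of leukocytes. Of 12 monocyte, macrophage and dendritic cell markers, 3 rose (2 adjusted over the list alone), LYZ by 0.33, C1QC by 0.25 and MARCO by 0.22, and the list did not pass camera (adjusted p = 0.241). The T and NK cell markers CD6 and CD5 rose by 0.24 and 0.13, which are 2 of 8 measured, also adjusted over the list alone (camera adjusted p = 0.321). Of 9 B and plasma cell markers, CD79A (0.33) and MZB1 (0.14) rose and SDC1 and BLNK fell by 0.45 and 0.19, with 5 rises and 2 falls adjusted over the list alone (camera adjusted p = 0.518). Among 4 mast cell and eosinophil markers, the 2 that rose were IL5RA by 0.25 and HDC by 0.24, also adjusted over the list alone (camera adjusted p = 0.441), and both calls were lost without the array labelled poly I:C 7.3 (adjusted p = 0.0581 and 0.0520). Of 14 fibroblast, smooth muscle and cartilage markers, the 5 that rose were DCN by 0.55, COL3A1 by 0.46, COL1A2 by 0.36, MYH11 by 0.17 and PDGFRB by 0.16, also adjusted over the list alone (camera adjusted p = 0.335). The endothelial markers PLVAP and ROBO4 rose by 0.13 and 0.12 (2 of 8, neither adjusted over the list alone, camera adjusted p = 0.774). The pan-leukocyte marker PTPRC was 0.17 higher (SE 0.14, adjusted p = 0.368). The 7 neutrophil markers (camera adjusted p = 0.902) and the 2 erythrocyte markers (camera adjusted p = 0.778) did not pass in limma, also adjusted over the list alone. The neutrophil list mean differed by -0.31, -0.42, -0.11 and -0.34 in animals 3, 6, 7 and 9 and by 0.14 to 0.28 in the others, but by 0.09 in animal 7 without the array labelled poly I:C 7.3. S100A9 differed by -0.18 (SE 0.19), CSF3R by -0.05 (SE 0.11), HBB by -0.20 (SE 0.28) and ALAS2 by -0.02 (SE 0.14).

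**Figure D2:**
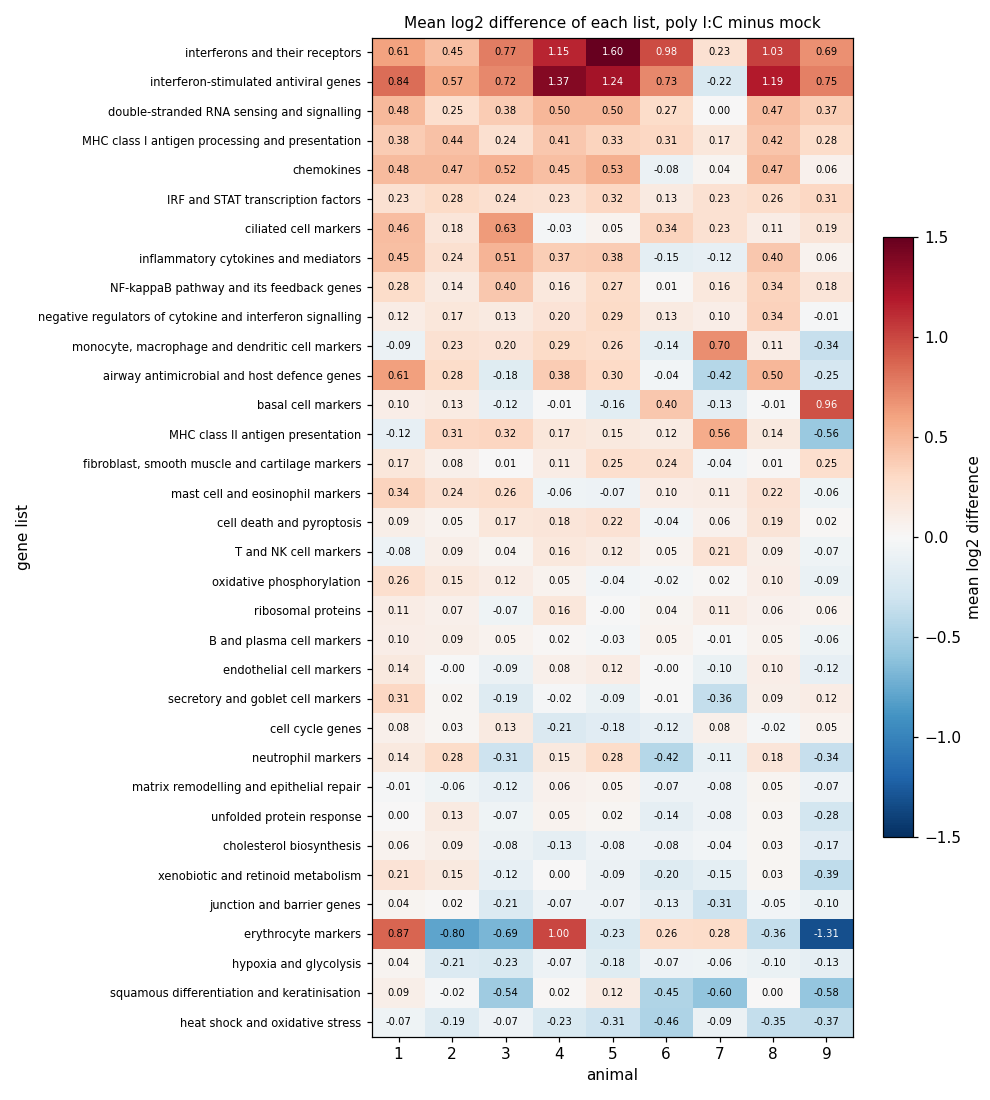
Mean log2 difference, poly I:C minus mock, over the measured members of each of 34 gene lists (rows) in each of 9 animals (columns), with red for higher and blue for lower after poly I:C. The interferon-stimulated row lies between 0.57 and 1.37 in 8 animals and at -0.22 in animal 7, which is 0.15 without the array labelled poly I:C 7.3.

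The response differed between animals for 1087 probe sets, 6.08% of those tested (interaction F-test in limma, adjusted p under 0.05). Of these, 389 were also changed on average, which is no larger a share than the 36.7% of all probe sets tested. MYBPC1, a myosin-binding protein, differed by -3.41, -2.53, -2.79 and -3.86 log2 in animals 3, 6, 7 and 9 and by between -0.03 and 0.33 in the others. HOXD1, a homeobox gene, differed by -2.41, -1.58, -1.41 and -2.23 in these 4 animals and by between -0.12 and 0.13 in the others. The basal keratin KRT5 was 1.99 higher in animal 6 and 3.33 higher in animal 9, and differed by between -0.73 and 0.12 elsewhere. ISG15 differed by -0.23 in animal 7, or 0.05 without the array labelled poly I:C 7.3, and by 1.10 to 2.08 in the others. The remaining genes with the smallest interaction p were NUPR1 (-1.39 to 0.98 across animals), DMRTA2 (-0.15 to 1.60), IGFBP3 (-1.99 to 0.39), PIGR (-1.16 to 0.70), RARRES1 (-2.03 to 0.72) and FBXO32 (-1.70 to 0.59). The error of this test is technical, and the count depends on few arrays: it was 1885 without the array labelled poly I:C 7.3, 1825 without animal 7, and 678, 198 and 588 without technical replicate 1, 2 and 3.

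**Figure D3:**
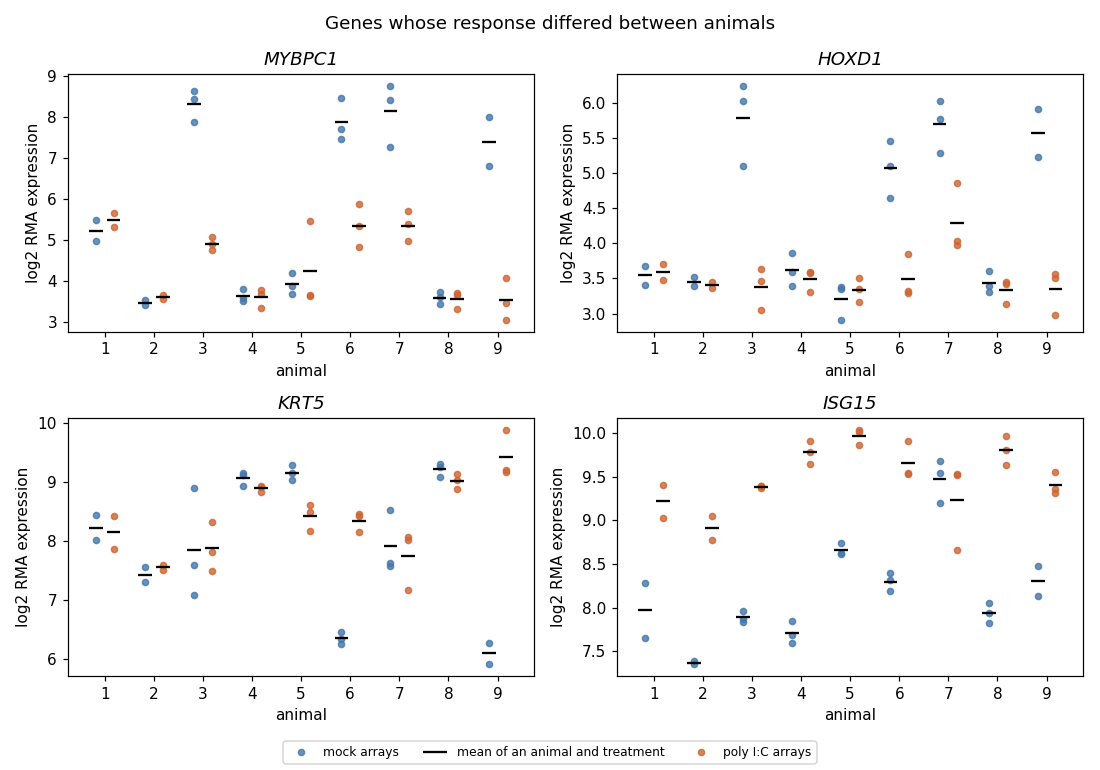
Expression of 4 genes whose response differed between animals, in log2 RMA units (vertical axis) by animal (horizontal axis), with mock arrays in blue, poly I:C arrays in orange, and a bar at the mean of each animal and treatment. Mock levels of MYBPC1 and HOXD1 are high in animals 3, 6, 7 and 9, mock levels of KRT5 are low in animals 6 and 9, and mock levels of ISG15 are high in animal 7.

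Within single animals, between 187 and 1577 probe sets were higher and between 111 and 1558 lower, with animals 3, 6 and 9 at the top. The 187 and 111 came from animals 2 and 1, which had 2 arrays per treatment, so the counts do not rank the responses. Animal 5, with 3 of each, had 246 higher and 155 lower. Animal 7 had 251 higher and 760 lower, or 1040 and 1800 without the array labelled poly I:C 7.3. The interferon-stimulated list rose by a mean of 0.57 to 1.37 log2 in 8 animals and differed by -0.22 in animal 7 (technical SE 0.41), or 0.15 without the array labelled poly I:C 7.3 (technical SE 0.18). Its mean in mock wells was 7.45 in animal 7 and between 5.51 and 6.09 in the others. After poly I:C the list mean was 7.23 in animal 7, or 7.61 without that array, and between 6.08 and 7.33 in the others. Over all probe sets, the median share of the sum of squares was 35.0% for animal, 6.67% for treatment, 12.2% for their interaction and 37.2% for technical replicates. Among the interferon-stimulated genes these shares were 56.1%, 15.7%, 11.6% and 12.1%. None is corrected for degrees of freedom, which differ between the sources, so the shares do not rank them. The animal, treatment and interaction shares also include technical spread.

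Whether the state of an animal's mock wells went with its interferon-stimulated response was tested with 6 correlations over the 9 animals. The mock level is that of parallel wells, not of the tissue before stimulation. The mock level of the interferon-stimulated list had a Pearson r of -0.74 with the response (exact permutation p = 0.072, adjusted p = 0.169) and a Spearman rho of -0.20 (exact permutation p = 0.613, adjusted p = 0.708). Without animals 7 and 5, the farthest from the median, r was -0.30, and without animal 7 alone it was 0.15. With the mock level and the difference taken from different technical replicates, r was -0.70 (exact permutation p = 0.085) and rho was 0.00. The mock level of double-stranded RNA sensing genes gave r = -0.72 and rho = -0.32 (exact permutation adjusted p = 0.169 and 0.708), and r = 0.29 without animals 7 and 6. Ciliated markers gave r = 0.60 and rho = 0.60 (exact permutation adjusted p = 0.169 and 0.290), and r = 0.68 without animals 5 and 3. Basal markers gave r = 0.50 and rho = 0.62 (exact permutation adjusted p = 0.218 and 0.290), and r = 0.48 without animals 9 and 5. Macrophage markers gave r = -0.49 and rho = -0.17 (exact permutation adjusted p = 0.218 and 0.708), and r = 0.21 without animals 8 and 7. Secretory markers gave r = 0.15 and rho = -0.15 (exact permutation adjusted p = 0.721 and 0.708), and r = 0.36 without animals 1 and 2. None passed after adjustment over the 6, two-sided, and the negative relations rest on animal 7. Without animal 7 alone, r was 0.02 for double-stranded RNA sensing, 0.46 for ciliated, 0.80 for basal, -0.08 for macrophage and -0.12 for secretory markers. No p-value was computed for these. With CXCL10 as the response, r was -0.85 for interferon-stimulated and -0.88 for sensing genes (exact permutation adjusted p = 0.079 and 0.068). It lay between -0.53 and 0.45 for the other lists.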

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

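The tests in the animal 7 paragraphs, and all values without the array labelled poly I:C 7.3, were chosen after the results were seen, except the comparison of array correlations.

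Over 53 named genes and 34 lists, 13 of 87 sets of 9 animal differences had an animal far from the rest, where chance gives about 1 in 20. The sets share animals and genes and are not independent. Some genes were named for a small interaction p or for moving alike in all animals, and that rate does not hold for them. Animal 7 lay lowest for the interferon-stimulated list (gap over range 0.498), double-stranded RNA sensing (0.499), CXCL10 (0.543), ISG15 (0.579), RIGI (0.609), IFIT2 (0.663), OASL (0.537) and AP2B1 (0.564), and highest for PTPRC (0.529). The IRF and STAT list was lowest in animal 6 (0.520), TNFAIP3 highest in animal 3 (0.515), and basal markers (0.499) and DMRTA2 (0.499) highest in animal 9. Without the array labelled poly I:C 7.3 the number was 7, of which 6 were among the 13: ISG15 (0.519), RIGI (0.534), IFIT2 (0.590), PTPRC (0.671), TNFAIP3 (0.515) and DMRTA2 (0.499). The interferon-stimulated list (0.344), double-stranded RNA sensing (0.223), CXCL10 (0.347), OASL (0.424), AP2B1 (0.240), IRF and STAT genes (0.345) and basal markers (0.480) then no longer stood apart, and monocyte and macrophage markers did (0.567, highest in animal 7). The response differed between animals for 1087 probe sets by the interaction test.

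The mean of the interferon-stimulated list did not rise in animal 7 (-0.22), although IFIT2, OASL and HERC5 were higher by 0.14, 0.25 and 0.35, or 1.24, 1.15 and 0.91 without the array labelled poly I:C 7.3. Removing the array labelled poly I:C 7.3 left 0.15 (technical SE 0.18), still below the lowest other animal at 0.57 by more than that SE. That array therefore carries part of the pattern. Whether unstimulated RNA on it accounts for the whole is not settled. Some animal must be lowest, the SE is technical only, and without the array the list no longer stood apart (gap over range 0.344). Poly I:C in the mock wells is argued against by a response score built from 529 probe sets outside the immune lists, set to 0 at the mean of other mock arrays and 1 at the mean of other poly I:C arrays: the mock arrays of animal 7 scored at most 0.191. What the tables hold is a mock level of the list 1.37 log2 above the highest other animal, while IFNL1 and IL6 were still higher after poly I:C in animal 7, by 1.57 and 0.92, or 2.38 and 0.97 without that array. An interferon response already present in this animal's tissue is a candidate explanation, found and tested on the same data, but a different share of leukocytes was not tested and stays open: its mock wells had the highest monocyte (5.98) and neutrophil (6.99) list levels of the 9 animals, and the poly I:C arrays behind the 0.15 had monocyte levels of 7.61 and 6.56 against 5.71 to 6.49 in its mock arrays, the former with the lowest mean correlation of the 49 arrays (0.885).

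The array labelled poly I:C 7.3 had less IFIT2 (7.73) than the other poly I:C arrays of animal 7 (11.05 and 10.95) and than its mock arrays (8.99 to 10.50), and its IFNL1 (4.44, against 6.79 and 6.99) lay within the range of the mock arrays (4.02 to 5.24). A swap with a mock array of animal 7 needs a mock array that responds, and the highest, mock 7.3, scored 0.191. Mock 7.3 and poly I:C 7.1 were, however, each other's nearest array, so a swap is not excluded. Poor RNA or hybridisation of the array labelled poly I:C 7.3 is argued against by its mean correlation with the other arrays, since 47 of 49 arrays had a lower one. A wrong label or an unstimulated well cannot be told apart from a partial response, because the array scored 0.380, within the range of other animals' mock arrays (-0.31 to 0.56), with 0.133 on the rising and 0.569 on the falling part, and lay below the mock arrays of animal 7 for the interferon-stimulated list (6.48 against 7.21 to 7.69), MYBPC1 (4.97 against 7.27 to 8.75) and HOXD1 (4.04 against 5.29 to 6.03), unlike an unstimulated well of this animal, though 1 array does not settle it. By deviations from the mean of all arrays, 47 of 49 arrays correlated best with an array of their own animal. On the 1000 most variable probe sets the number was 48. The array labelled poly I:C 7.3 was outside both counts, and its nearest array was a mock array of animal 9. RNA from another animal, or a mixture, was not tested, and the array was kept under its label.

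A control probe set outside the main measurement moved with the treatment. The 5' control set for ACTB was 0.119 lower after poly I:C (0 of 9 animals higher, exact two-sided sign-flip permutation p = 0.00391, the smallest that 9 animals allow), and its 3' partner was not analysed here. RNA quality or labelling that differed between treatments was therefore not excluded, which bears on the 6232 called changes under 1.5-fold.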

How the results depend on the processing

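The array labelled poly I:C 7.3 and animal 7 were left out of tests after the data were seen. None of the 154 genes and 34 lists run under the alternatives reversed past its threshold (genes named only as members of a small count were not run), but 21 of the 6556 called probe sets changed sign with only the lowest shared technical replicate. Leaving out 1 animal at a time gave 2406 to 2810 probe sets higher, 3065 to 3479 lower and 43 to 56 changed 2-fold or more. Counts moved over 1.5 times with no replicate block (1652 higher, 1936 lower, and 3581 of the 6556 calls kept), with only the lowest shared technical replicate (1177 and 1883), without the dimmer 50% of probe sets (1587 and 2097, and 32 changed 2-fold or more, with fewer probe sets tested), and at an adjusted p under 0.01 (1520 and 2160). With arrays centred on their median, 48.5% of calls were higher, against 45.1%. Pairing arrays by animal and technical number called 3762 and 4344. Without animal 7, list counts moved, and the following are examples. Falls of inflammatory mediators went from 3 to 1 and of chemokines from 1 to 0. Rises of MHC class II genes and of mast cell and eosinophil markers went from 2 to 1 and of junction genes from 1 to 2. B cell rises and falls went from 2 to 1 each. Rises of ciliated markers went from 18 to 14 and of interferon-stimulated genes from 34 to 39. Of 3315 comparisons of 154 named genes with their alternatives, 286 lost the threshold and 12 gained it.

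With an estimated correlation all 8 list calls were lost: adjusted p was 0.702 for interferon-stimulated genes, chemokines and ciliated markers, 0.479 for double-stranded RNA sensing and MHC class I, 0.063 for IRF and STAT genes, and 0.696 for NF-kappaB and heat shock genes. The estimates include what the members share across animals (correlation 0.682 for interferon-stimulated genes), and without animal 7 all 8 stayed lost (lowest adjusted p 0.212, and 0.536 at a correlation of 0.512 for interferon-stimulated genes), so animal 7 alone is not the cause. Fry gave adjusted p of 0.0153 for interferon-stimulated genes and 0.0224 for ciliated markers. Chemokines were also lost without the block (0.145) and, among animals left out in turn (0.00155 to 0.0502), without animal 5, NF-kappaB genes without the block (0.0704), and double-stranded RNA sensing without members of 2 lists (0.230); the cause was not tested. The block changed no other list call.

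The count of differing responses fell to 678, 198 and 588 without technical replicate 1, 2 and 3, with fewer arrays and a lone array in some animals assumed to vary like the others. It rose to 1885 without the array labelled poly I:C 7.3 and to 1825 without animal 7. The correlations across animals stayed on their side of the threshold with 2 animals left out and with CXCL10 as the response. An offset before log2 was not run because the table was already on a log scale. Signal over background could not be measured from this table, so dim probe sets were not told apart from absent transcripts.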

Other observations

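The tests of probe sets of the same gene were set before their results were seen.

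The stress and metabolic lists of this paragraph did not pass camera. Of 18 unfolded protein response genes, TRIB3, CHAC1, SESN2 and DNAJC3 fell by 0.45, 0.35, 0.18 and 0.16 (4), and PPP1R15A and SDF2L1 rose by 0.37 and 0.19 (2), with a camera adjusted p = 0.643. Of 16 hypoxia and glycolysis genes, 5 fell: NDRG1 by 0.44, ADM by 0.31, VEGFA by 0.27, PFKP by 0.25 and PDK1 by 0.21 (camera adjusted p = 0.061). Fry passed for this list (adjusted p = 0.0153), whose mean was higher in 1 of 9 animals. Among 13 cholesterol synthesis genes SQLE, SC5D and NSDHL fell by 0.41, 0.40 and 0.14 (3), while LSS, HMGCS1 and MVD rose by 0.30, 0.30 and 0.16 (3, camera adjusted p = 0.335). Of 22 xenobiotic and retinoid genes, 6 fell, including the aryl hydrocarbon receptor targets CYP1A1 (by 0.70) and CYP1B1 (by 0.66), and 4 rose, FMO2 by 0.42, EPHX1 by 0.37, CYP2A13 by 0.37 and PLAAT4 by 0.34 (camera adjusted p = 0.643). Adjusted over the list alone, the first 3 of these lists kept their counts, and the xenobiotic list had 7 falls and 5 rises.

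Of 17 oxidative phosphorylation genes, CYC1 (0.24), NDUFB5 (0.23) and ATP5F1B (0.13) rose (3, or 1 adjusted over the list alone, camera adjusted p = 0.321). Among 10 cell cycle genes, CCNE2, CCNA2 and MCM4 fell by 0.53, 0.23 and 0.17 (3), and UBE2C and MCM3 rose by 0.28 and 0.19 (2); the median difference was 0.03 and the mean -0.02 (camera adjusted p = 0.913). Of 21 matrix and repair genes, TGFA, TGFB2, THBS1, EGFR and CCN2 fell by 0.39, 0.38, 0.28, 0.21 and 0.20 (5), and PLAUR and MMP14 rose by 0.33 and 0.20 (2, camera adjusted p = 0.549). Of 24 cell death genes, 9 rose, with BCL2A1 at 0.74, BAX at 0.46 and PMAIP1 at 0.39, and BCL2L11, APAF1 and BCL2L1 fell by 0.30, 0.20 and 0.17 (3, camera adjusted p = 0.175). Of 20 airway defence genes, 7 rose, with the complement factor CFB at 0.64 and the defensin DEFB1 at 0.40 (camera adjusted p = 0.310). Of 11 MHC class II genes, RFX5 and HLA-DMB rose by 0.25 each (2, camera adjusted p = 0.361). No ribosomal protein gene passed in limma among 5 measured; RPS6 differed by 0.00 and RPL19 by 0.05 (camera adjusted p = 0.492). Counts adjusted over the list alone were the same for these lists except the oxidative phosphorylation list. Other lists that passed fry but not camera, all upward, were interferons and receptors (adjusted p = 0.0180), negative regulators (0.00476), cell death (0.0180), T and NK cell markers (0.0277) and B and plasma cell markers (0.0224).

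The mock wells of animals 3, 6, 7 and 9 held MYBPC1 at 8.32, 7.87, 8.14 and 7.40 log2, against 3.48 to 5.23 in the other animals, and all 9 poly I:C means lay between 3.53 and 5.49. HOXD1 in mock wells was 5.79, 5.07, 5.70 and 5.58 in these animals and 3.21 to 3.62 in the others, with poly I:C means of 3.34 to 4.29. IGFBP3 was 8.89, 8.11, 8.10 and 8.49 against 6.52 to 7.45. The airway defence list, chosen after its values were seen, had mean differences of -0.18, -0.04, -0.42 and -0.25 in these animals and 0.28 to 0.61 in the others. No label distinguishes these animals, so no test was made.

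Probe sets of the same gene disagreed on the rise after poly I:C more often outside the immune lists. SMAD3, chosen after its values were seen, rose by 1.44 on a single probe set, while its other 3 probe sets had differences of 0.04, 0.00 and -0.15. Among 105 genes with several probe sets of which the highest rose by at least 0.5, the other probe sets showed a median of less than 0.25 of that rise in 32.9% of 85 genes outside the immune lists and in 5% of 20 inside (28 and 1 genes, 95% intervals 23.1 to 44.0 and 0.127 to 24.9, Fisher's exact test, p = 0.0116), and the share among 125 falling genes was 14.4%. The 32.9% is what would be seen if part of the rises outside the immune lists belonged to single probe sets. Unannotated transcript ends or cross-hybridisation would give such a signal, and no sequence was at hand to test this. The genes inside and outside were not matched for the number of probe sets or the size of the rise, and both bear on this share. The largest rise was 4.63 inside and 1.55 outside. Dimness of the other probe sets stays open: the share was 45% of 40 genes when only siblings at least as bright were used, but the signals of different probe sets on this array do not rank them by abundance or sensitivity, so this value decides nothing.

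Chance exchange of the treatment labels within animals can be excluded as the source of the counts: among 100 of the 256 exchanges, only the real one (1 of 100) gave as many calls, with 2960 higher and 3596 lower against at most 924 in the others, and 52 changed 2-fold or more against at most 16.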
